A study of Arabidopsis thaliana with 24 samples.

How the data were processed

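Whole Arabidopsis thaliana seedlings (root, hypocotyl and cotyledon together), 4 days old and grown in darkness, were profiled on Affymetrix arrays carrying 22810 probe sets, each a set of short oligonucleotides for one transcript or a few. Seedlings stayed in the dark or received continuous red light (680 nm, 8 µmol per square metre per second) for 1 h, in wild type and in mutants lacking phytochrome A (phyA), phytochrome B (phyB) or both (phyAphyB). The labels give 3 dark and 3 red-light biological replicates for each genotype, 24 arrays in 8 groups. The p-values measure spread between these samples. Alleles and parental strains are not given in the sources used here.

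The deposited values are intensity values, 1 signal per probe set and array on a linear scale, and the submitters' processing notes name MAS5, the Affymetrix signal algorithm, with no version. The mean signal after trimming 2% at each end lay between 500.038 and 500.044 on all 24 arrays, so the values were taken as already scaled and were kept. Detection calls, scanner files and the scaling target were not used here. Such scaling assumes that the mean signal is the same in every sample, and MAS5 signals of dim probe sets vary widely on a log scale.

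From these values, 64 Affymetrix control probe sets were left out of the tests. A probe set was tested where its signal exceeded the array's own 40th percentile on at least 3 of the 24 arrays, which left 15085 probe sets. The log2 signal was taken without a pseudocount. 4 values of 0 in the whole table would have been replaced by 0.05, and 0 of them were among the tested probe sets. Of 22746 probe sets without the controls, 13513 were paired with 1 gene, 503 with several and 8730 with none in the probe table used here. Symbols were updated through NCBI gene identifiers of the TAIR10.1 assembly, with 77 loci unmatched. Among the tested probe sets 8185 had 1 gene and stood for 8103 genes, 304 had several and 6596 were unnamed. Many well-known light genes, PHYA and PHYB included, were among the unnamed and were not analysed here, so the mutated genes could not be used to check the labels. No build was named for the probes, so no coordinates are given, and the TAIR10.1 gene table was used for names and gene order only.

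A mean for each of the 8 groups was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), so that every contrast shared 1 estimate of the spread. All tests were two-sided with Benjamini-Hochberg adjustment over the tested probe sets, and a call needed an adjusted p under 0.05. A second count also needed a change of at least 2-fold. The contrasts were red minus dark within each genotype, the difference of that response between genotypes, the non-additivity of both mutations, a joint F-test of the 3 differences from wild type, and mutant minus wild type in the dark. The retained share is the median, over probe sets called at 2-fold or more in wild type, of the mutant log2 response divided by the wild type log2 response. Its 95% interval comes from 2000 bootstrap draws of probe sets and is descriptive, because probe sets are not independent replicates. Choosing probe sets by a large wild type response overstates that response and so lowers the share. For this reason a held-out wild type replicate was also used.

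Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 3 members were measured. 17 lists with 336 members were fixed before the data were examined, together with the design, the naming rule and the alternatives below that are not said to be added. Of those members 46 had a named probe set and 43 were tested. Gene families taken from symbols were added after the probe names had been seen. The naming rule took the 12 largest rises and 8 largest falls of the wild type response among calls with 1 gene, no overlap between dark and red arrays and the brighter group mean above the median signal. For each other contrast it took 4 rises and 4 falls by the same criteria, without the overlap criterion for differences of responses, and up to 4 called members of each list. A gene with several probe sets is given by the brightest one.

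The alternatives were quantile normalization, no filter, a filter at the 60th percentile, a pseudocount of 34.8 signal units, no intensity trend, a fit of the compared groups alone, the replicate number as a block, the leaving out of each array in turn, and a held-out wild type replicate for the retained share. Array weights and the leaving out of dark phyA replicates 2 and 3 were added after the data had been seen. Gene positions were tested on 8009 genes in 162 bins of up to 50 neighbours against 10000 shuffled gene orders, and within 100 measured genes on each side of PHYA and PHYB.

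The procedure was tested on simulated data with the real spread of each probe set, taken as equal on all arrays and independent between probe sets. With 200 of 15085 probe sets changed, the wild type light contrast recovered 47.8% of 1.5-fold, 76.1% of 2-fold and 98.5% of 4-fold changes, with 3.3% false calls. A difference of responses recovered 14.9%, 62.7% and 89.4%, with 2.6% false calls, and dark phyA against wild type 46.3%, 80.6% and 97%, with 5.7% false calls. The number of arrays limits the precision: the median SE was 0.167 log2 units for a contrast of 2 groups and 0.236 for a difference of responses. Figures were drawn with matplotlib 3.10.9.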

Results

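The data hold 24 arrays, 3 for each of 4 genotypes in darkness and after 1 h of red light. Median signals ranged from 169.8 to 195.1 and the correlation of an array with the others of its group from 0.954 to 0.981. The lowest correlation belonged to dark phyA replicate 1. A control probe set for 25S ribosomal RNA read 10510 and 13570 on dark phyA replicates 2 and 3, against 46.8 to 450 on the other 22 arrays. Values below are log2 changes with their SE from limma, n = 3 per group, unless a signal is given with its SD.

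The response of wild type to 1 h of red light is described first by single genes of known function. HYH, a bZIP factor closely related to the light regulator HY5, rose 13.4-fold (log2 3.75 ± 0.63, adjusted p = 0.00024), from a signal of 19.1 ± 11.2 to 218 ± 17.2. SNZ, an AP2-type repressor of flowering, rose 8.75-fold. The flavonoid glycosyltransferase genes AT1G06000, a flavonol rhamnosyltransferase, and UGT78D2, a flavonoid 3-O-glucosyltransferase, rose 8.11-fold and 3.86-fold. IAA29, an Aux/IAA repressor of auxin responses, fell 6.14-fold (log2 -2.62 ± 0.20, adjusted p = 1.7e-09), and EXO, a brassinosteroid-responsive growth gene, fell 5.65-fold (log2 -2.50 ± 0.15).

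The other large rises were AT3G02910 (log2 3.19 ± 0.23), the glutaredoxin family gene AT1G64500 (2.97 ± 0.20), the polygalacturonase gene AT1G48100 (2.91 ± 0.51), AT5G15950 for S-adenosylmethionine decarboxylase (2.25 ± 0.14), the nitrate transporter gene AT3G21670 (2.2 ± 0.19), MSRB6 for a methionine sulfoxide reductase (2.11 ± 0.26), AT4G24700 (1.98 ± 0.22) and AT1G73480 (1.92 ± 0.12). The other large falls were AT5G02580 (-2.42 ± 0.18), AT4G35720 (-1.92 ± 0.18), AT5G57670 (-1.90 ± 0.48), the glutaredoxin gene AT5G18600 (-1.74 ± 0.20), AT4G10910 (-1.72 ± 0.14) and AT4G16670 (-1.57 ± 0.16). These genes follow the naming rule, which required that the 3 red arrays lie beyond the 3 dark arrays. The rule left out other large called changes, such as those of AT3G53250 (-3.51) and AT1G18810 (2.48). Dark signals of 19.1 for HYH, 40.6 for AT1G48100, 55.2 for SNZ, 76.3 for MSRB6, 85.4 for AT1G06000 and 96.9 for AT1G64500 lay under every array's 40th percentile (97.4 to 127.2), as did the red signal of AT5G57670 (89), so the size of these folds is uncertain. The fall of AT5G57670 missed the threshold without red wild type replicate 2 (log2 -1, adjusted p = 0.13) and without dark wild type replicate 3 (log2 -1.87, adjusted p = 0.052).

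Of the 43 measured members of the fixed lists, 2 rose, 7 fell and 34 did not pass in wild type, and 10 passed when adjusted over the list alone. Auxin response genes were lower as a group (4 measured, median log2 -0.64, camera adjusted p = 0.00017, and adjusted p = 0.004 with an estimated correlation). IAA29 and GH3.3, which encodes an auxin-conjugating enzyme, fell by 2.62 and 1.08, and WES1 and YUC2 did not pass. Expansin and xyloglucan endotransglucosylase genes, which loosen cell walls, were also lower (7 measured, median -0.34, camera adjusted p = 0.0061), a call lost at adjusted p = 0.16 with an estimated correlation. The wider family of 20 such genes, added later, did not pass (median -0.10, camera adjusted p = 0.21), with 1 higher and 3 lower. EXPB1 (-1.01 ± 0.18) and XTH33 (-0.92 ± 0.21) fell and 5 others did not pass. XTH33 missed the threshold without red wild type replicate 1 (log2 -0.68, adjusted p = 0.064).

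Single measured regulators moved as well. The clock gene GI rose by 0.87 ± 0.13. FHL, a partner of phytochrome A in nuclear import, fell by 0.86 ± 0.19 and the shade-induced HAT2 fell by 0.93 ± 0.14. PORB, a protochlorophyllide oxidoreductase gene, fell by 0.72 ± 0.15, while the other 7 measured genes of chlorophyll synthesis did not pass (camera adjusted p = 0.14). No member passed among 3 antenna protein genes (camera adjusted p = 0.81), 5 photosystem and carbon fixation genes (0.81), 4 gibberellin genes (0.81) and 3 reference genes (0.99). The lists with 1 measured member that did not pass gave log2 changes of 0.51 for UF3GT in the flavonoid list, -0.09 for EIN3 in the ethylene and brassinosteroid list, 0.05 for STZ among handling genes, -0.37 for the root marker EXPA18 and -0.14 for ICL in the seed reserve list. Photoreceptor and sigma factor lists had 0 measured members.

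Over all tested probe sets limma called 973 in wild type, 612 higher and 361 lower in red light, of which 229 rises and 74 falls were at least 2-fold. Among called probe sets with no gene name, the largest changes were rises of 6.10 ± 0.71 and 4.37 ± 0.20 and a fall of 2.64 ± 0.31. Here the brightness criterion was kept and the overlap criterion was not used.

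**Figure D1:**
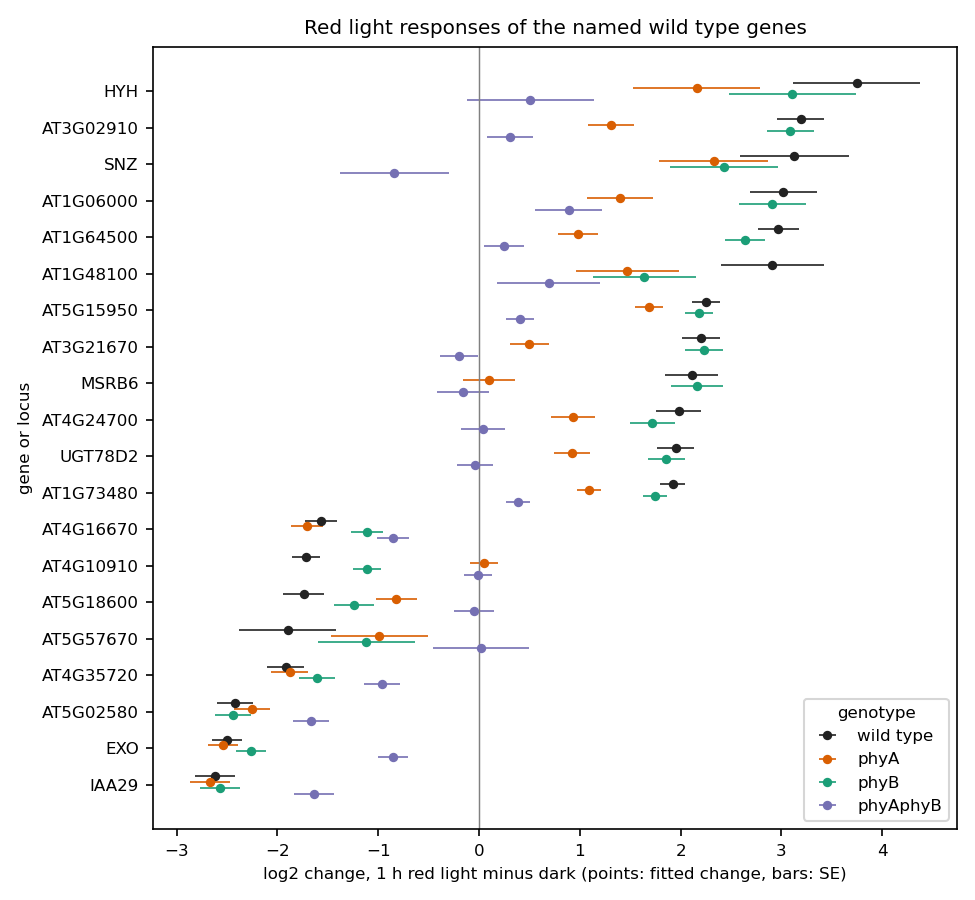
Fitted log2 change from dark to 1 h of red light for the 20 named wild type genes in each genotype, with points for the change and bars for the SE (n = 3 arrays per group). The phyB points lie near wild type for MSRB6 (2.16 against 2.11), where the phyA point is at 0.10 and the phyAphyB point at -0.16.

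The phyA mutant was compared to learn which red responses change without phytochrome A. Several strong rises were smaller. MSRB6 changed by 0.10 ± 0.26 in phyA, which differed from wild type by -2.01 ± 0.37 (limma adjusted p = 0.0084). AT1G64500 rose by 0.98 in phyA (difference -1.99 ± 0.28, adjusted p = 0.00037), AT3G02910 by 1.31 (difference -1.88 ± 0.32, adjusted p = 0.0035) and AT1G73480 by 1.09 (difference -0.83, adjusted p = 0.015). AT3G21670 changed by 0.50 in phyA (difference -1.70 ± 0.27, adjusted p = 0.0021). The fall of AT4G10910 was absent from phyA at 0.05 ± 0.14 (difference 1.78 ± 0.20, adjusted p = 3.4e-05).

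Other wild type genes responded in phyA with no detected difference. IAA29 fell by 2.67 ± 0.20, EXO by 2.54 ± 0.15 and AT5G02580 by 2.25 ± 0.18. AT5G15950 rose by 1.69 and AT5G47610 by 1.61. AT5G12110, an elongation factor gene, rose by 1.81 in wild type and changed by -1.14 ± 0.39 in phyA (difference -2.95 ± 0.56, adjusted p = 0.011), with log2 signals of 6.918, 4.678 and 4.711 on the 3 red phyA arrays. That red phyA signal (57.6 ± 54.8) lay under the arrays' 40th percentile of 97.4 to 127.2, and the compared groups alone gave an adjusted p of 0.075. A rise beyond wild type was called for AT5G53710 (1.54 in phyA, difference 1.21 ± 0.27, adjusted p = 0.033), LEA18 for a late embryogenesis protein (0.77, difference 1.19 ± 0.20) and AT3G20340 (0.58, difference 1.16 ± 0.22). The difference of AT5G53710 missed the threshold without any of dark phyA replicates 2 and 3, red phyA replicates 1 and 2, dark wild type replicates 1 and 2 or red wild type replicate 2 (7 of 12 fits, adjusted p up to 0.11). Without both dark phyA arrays of high ribosomal RNA signal it was 0.92 (adjusted p = 0.21), and those of LEA18 and AT3G20340 were 1.05 (0.051) and 1.14 (0.063), close in size to those from all arrays but with fewer arrays behind them. AT5G50360 rose by 1.74 ± 0.26 in phyA, and its difference from wild type did not pass. In dark phyA all 4 were below dark wild type, by 0.82 for AT5G53710, 0.54 for LEA18, 0.88 for AT3G20340 and 1.32 for AT5G50360. Of the dark phyA arrays, replicates 2 and 3 but not replicate 1 had the high ribosomal RNA signal.

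In phyA, 655 probe sets passed, 364 higher and 291 lower, and 162 were at least 2-fold. Of these, 217 rises and 127 falls were shared with wild type, where independent lists would share 14.8 and 6.96. The response differed from wild type for 100 probe sets, 28 higher and 72 lower. Over the 303 probe sets changed at least 2-fold in wild type, phyA retained a median of 53.3% of the response (interval 47 to 58.3), 48.9% of the 229 rises and 70.4% of the 74 falls. The counts depended on single arrays. The 655 became 1008 without dark phyA replicate 1, 401 without dark phyA replicate 2 and 413 without dark phyA replicates 2 and 3, and the compared groups alone gave 233. The 100 became 253 without dark phyA replicate 1, 60 and 56 without dark phyA replicates 2 and 3, 55 and 48 without dark wild type replicates 2 and 3, 50 and 65 without red wild type replicates 1 and 2, and 39 from the compared groups alone.

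The phyB mutant was compared to learn which red responses change without phytochrome B. HYH rose by 3.11 ± 0.63, AT3G02910 by 3.09 ± 0.23, AT1G06000 by 2.91 ± 0.33, AT1G64500 by 2.64 ± 0.20, AT3G21670 by 2.23 ± 0.19 and MSRB6 by 2.16 ± 0.26. IAA29 fell by 2.57 ± 0.20, AT5G02580 by 2.44 ± 0.18 and AT5G57760 by 1.68 ± 0.21, and the change of EXO was -2.26 ± 0.15. Other genes had smaller changes than in wild type, with differences that did not pass: 1.64 against 2.91 for AT1G48100, -1.14 against -2.60 for AT1G72290, -1.12 against -1.90 for AT5G57670 and -1.11 against -1.72 for AT4G10910. The auxin list was lower (median -0.47, camera adjusted p = 0.00091, and adjusted p = 0.0092 with an estimated correlation), as was the expansin list (median -0.20, camera adjusted p = 0.0041, and adjusted p = 0.14 with an estimated correlation).

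In phyB, 867 probe sets passed, 540 higher and 327 lower, of which 420 rises and 196 falls were shared with wild type against 21.9 and 7.83 for independent lists. limma found 0 probe sets whose response differed between phyB and wild type, with 604 of 15085 at an unadjusted p under 0.05, no more than chance gives. The retained share was 87.3% (interval 83.9 to 91.1), and 273 of the 303 probe sets passed in phyB in the same direction. On the dark and red phyB arrays of 1 replicate number at a time the share was 94, 77.5 and 88.2%, a wider range than that interval. The lack of calls does not show equal responses: simulated differences of 2-fold were recovered in 62.7% of cases and of 1.5-fold in 14.9%. Those simulations changed 200 probe sets in phyA and gave all arrays the same spread. With fewer changed probe sets the adjusted threshold is stricter, so recovery for phyB may be lower.

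Both single mutants were also compared directly. The change of MSRB6 was lower in phyA than in phyB (difference -2.06 ± 0.37, limma adjusted p = 0.0095), as were those of AT3G02910 (-1.78 ± 0.32, adjusted p = 0.0095), AT3G21670 (-1.73 ± 0.27, adjusted p = 0.0027) and AT5G12110 (-2.71 ± 0.56, adjusted p = 0.023). AT5G53710 (1.45 ± 0.27), AT1G44835 (1.27 ± 0.25), AT4G10910 (1.16 ± 0.20) and WAG2, a kinase gene of auxin transport (1.17 ± 0.23), had the higher change in phyA. WAG2 fell by 1.06 in phyB and changed by 0.11 in phyA. Its difference missed the threshold without dark phyB replicate 3 (1.12, adjusted p = 0.055) or red phyB replicate 1 (1.06, adjusted p = 0.06). Without both dark phyA arrays of high ribosomal RNA signal all 4 of these higher changes lost their calls: AT5G53710 differed by 1.15 (adjusted p = 0.096), AT1G44835 by 1.05 (0.14), AT4G10910 by 0.93 (0.091) and WAG2 by 1.18 (0.071). The call of AT5G12110 was lost there as well (-2.92, adjusted p = 0.061) and from the compared groups alone (adjusted p = 0.15). The difference of AT5G12110 missed the threshold without dark phyA replicate 2, red phyA replicates 2 and 3, dark phyB replicate 3 or red phyB replicates 1 and 3 (6 of 12 fits, adjusted p up to 0.072), and that of AT1G44835 without dark phyA replicates 2 and 3, red phyA replicates 1 and 2, dark phyB replicate 3 or red phyB replicate 3 (6 of 12 fits, adjusted p up to 0.077). In all, 81 probe sets differed, 22 higher and 59 lower in phyA. That count became 146 without dark phyA replicate 1, 45 and 47 without dark phyA replicates 2 and 3, 50 and 53 without red phyA replicates 2 and 3, 32 without dark phyB replicate 3, and 37, 51 and 48 without red phyB replicates 1, 2 and 3. It was 50 with no filter and 16 from the compared groups alone.

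**Figure D2:**
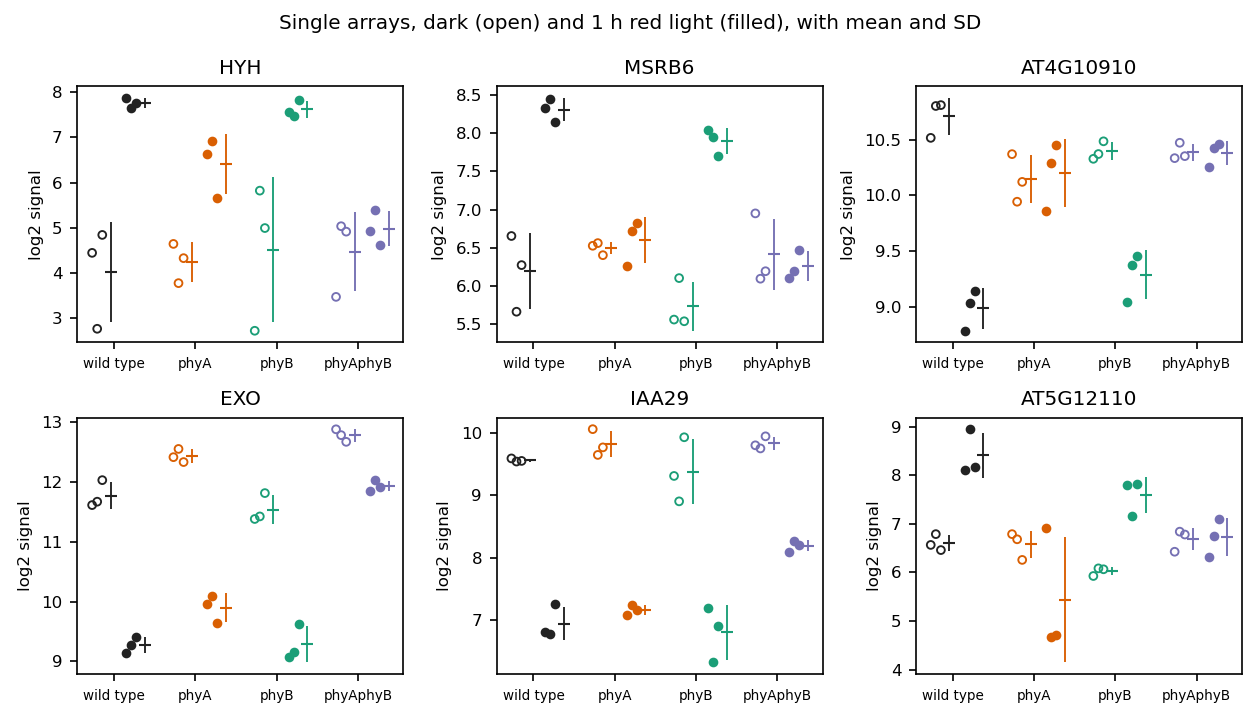
log2 signals of 6 genes on single arrays, open for dark and filled for 1 h of red light, with the group mean and SD beside them (n = 3). MSRB6 moved from a mean signal of 76.3 to 319 in wild type and from 90.5 to 98.5 in phyA, and IAA29 fell in all 4 genotypes.

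Without both phytochromes most of the response was lost. SNZ changed by -0.84 ± 0.54 in phyAphyB, against 3.13 in wild type (difference -3.97 ± 0.76, limma adjusted p = 0.0031). Differences of at least 1.5 log2 units were also called for AT3G02910 (-2.88 ± 0.32, adjusted p = 2.4e-06), AT1G64500 (-2.72), AT3G21670 (-2.40), MSRB6 (-2.27), AT1G06000 (-2.13), UGT78D2 (-1.99), AT4G24700 (-1.94), AT5G15950 (-1.83) and AT1G73480 (-1.52), whose responses in the mutant lay between -0.20 and 0.89 and did not pass. HYH changed by 0.51 ± 0.63, from a signal of 24.7 ± 11.8 to 32.4 ± 8.77, and its difference from wild type did not pass. Dark wild type signals of HYH, SNZ, MSRB6, AT1G06000 and AT1G64500 lay under every array's 40th percentile (97.4 to 127.2). AT1G06000 (58.8 ± 33.2) and AT1G64500 (75.9 ± 8.55) stayed under it in red phyAphyB, so the size of these differences is uncertain.

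Some falls were still called in phyAphyB. IAA29 fell by 1.64 ± 0.20 (adjusted p = 0.00023), AT5G02580 by 1.67 ± 0.18, AT5G57760 by 1.03 ± 0.21, AT4G35720 by 0.96 ± 0.18, EXO by 0.85 ± 0.15 and AT4G16670 by 0.85 ± 0.16. Of these only EXO differed from wild type (difference 1.65 ± 0.21, adjusted p = 1.7e-05). The falls of AT5G18600, AT4G10910, AT1G72290 for a Kunitz-type inhibitor, GH3.3 and HAT2 were reduced, with differences of 1.69, 1.71, 1.97, 1.02 and 0.80. The difference of AT1G72290 missed the threshold in 10 of 12 fits that left out 1 array, all but those without red wild type replicate 1 and dark phyAphyB replicate 1 (adjusted p up to 0.14), and was 0.77 with a pseudocount (adjusted p = 0.3). The fall of AT5G57760 missed it without dark phyAphyB replicates 1 and 2 or red phyAphyB replicates 1 and 2 (adjusted p up to 0.31), and that of AT4G35720 without dark phyAphyB replicates 1 and 3 or red phyAphyB replicates 1 and 3 (adjusted p up to 0.096). The auxin list was lower in the mutant (median -0.05, camera adjusted p = 0.02, and adjusted p = 0.044 with an estimated correlation), with IAA29 alone passing, and less so than in wild type (difference median 0.56, camera adjusted p = 0.0061, and adjusted p = 0.027 with an estimated correlation). The 3 antenna protein genes were higher as a group (median 0.34, camera adjusted p = 0.0047, and adjusted p = 0.024 with an estimated correlation), with 0 of 3 passing alone, and its difference from wild type (camera adjusted p = 0.046) was lost at adjusted p = 0.086 with an estimated correlation. The difference of the expansin list (median 0.40, camera adjusted p = 0.046) was lost at adjusted p = 0.29 with an estimated correlation. AT3G63340 and AT4G01910 were called for a fall of 2.47 and a rise of 1.58, at signals of 28.6 ± 6.16 or less and 30.4 ± 7.85 or less in this mutant, and with a pseudocount the difference of AT4G01910 was 0.65 (adjusted p = 0.28). The difference of AT3G63340 (-2.74) was lost from the compared groups alone (adjusted p = 0.1).

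In phyAphyB, 46 probe sets passed, 4 higher and 42 lower, and the count was 24 and 30 without dark phyAphyB replicates 1 and 3, 25, 26 and 27 without red phyAphyB replicates 1, 2 and 3, and 24 from the compared groups alone. Of the 42 falls, 36 were also falls in wild type, against 1.01 for independent lists. The response differed from wild type for 282 probe sets, 53 higher and 229 lower. The retained share was 12% (interval 10 to 15.6), 9.7% of the rises and 33.3% of the falls. On the dark and red phyAphyB arrays of 1 replicate number at a time, the rises retained 4.6, 10.4 and 13.3%. The falls retained 42.8, 31 and 28.6% on the same arrays, so the size of the gap varied between replicates. Of the 43 measured list members, 6 passed in phyA, 8 in phyB and 1 in phyAphyB, and 10, 10 and 5 when adjusted over the list alone. For differences from wild type the counts were 0, 0 and 2, and 2, 0 and 8 when adjusted over the list alone.

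**Figure D3:**
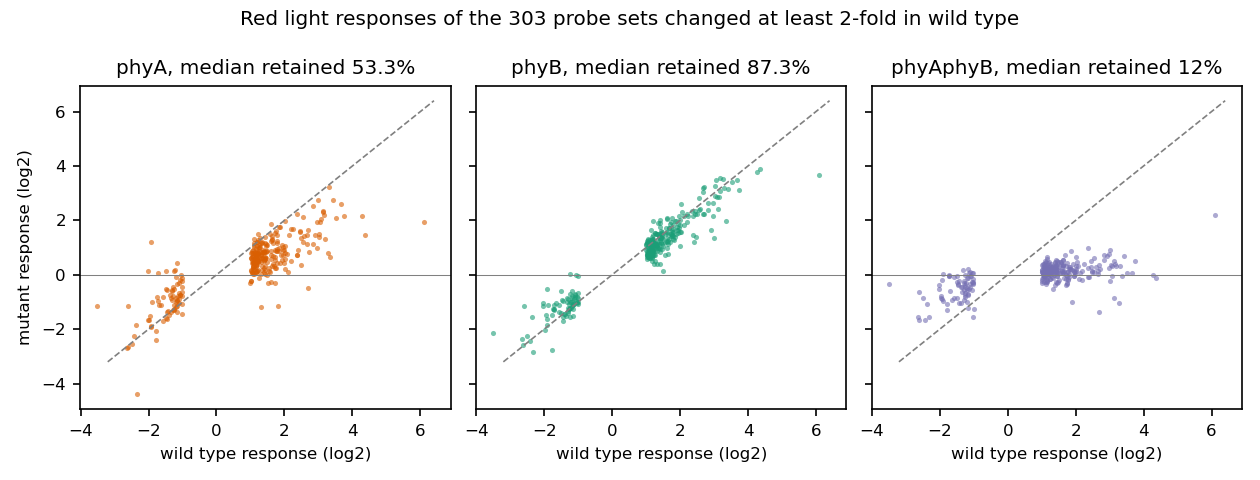
Mutant against wild type log2 response for the 303 probe sets changed at least 2-fold in wild type, 1 point per probe set, with the dashed line marking equal responses. The median retained share was 53.3% in phyA, 87.3% in phyB and 12% in phyAphyB.

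Across all 4 genotypes, the joint limma F-test called 343 probe sets whose red response depended on the genotype. Non-additivity of both losses was called for 5 probe sets, none of them with a gene name. The first, chosen after its values were seen, rose by 3.3 in wild type, 3.23 in phyA and 3.2 in phyB and changed by 0.31 in phyAphyB (non-additivity -2.82 ± 0.52, adjusted p = 0.049). With the adjusted p just under the threshold, the count was 0 with no filter, 0 with no intensity trend, 1 with the replicate block, and between 0 and 21 when single arrays were left out.

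The mutants differed from wild type before any red light. In dark phyA, AT2G01090 was higher by 3.61 ± 0.50 (signals 439 ± 39.5 against 51.0 ± 48.5, adjusted p = 0.00013), AT1G12730 by 1.84 ± 0.26, AT2G14800 by 1.73 ± 0.27 and AT1G12400 by 1.71 ± 0.46, and AT1G05340 was lower by -1.47 ± 0.12, AT1G68250 by -1.34 ± 0.34, AT5G50360 by -1.32 ± 0.26 and AT1G06200 by -1.18 ± 0.13. In dark phyB, AT2G25450, a dioxygenase gene of glucosinolate side-chain hydroxylation, was lower by -3.72 ± 0.32 (signals 1030 ± 957 against 10300 ± 540, adjusted p = 2.2e-08), AT5G23830 by -4.85 ± 0.63, AT4G19500 by -3.62 ± 0.67 and PIP, a prolyl iminopeptidase gene, by -2.69 ± 0.18. AT3G47320, AT1G23960, AT5G27750 and AT4G29200 had signals of 1310 ± 102, 1920 ± 218, 195 ± 34.7 and 1860 ± 122 in dark phyB, against 25.6 ± 42.8, 60.5 ± 96.0, 12.2 ± 9.64 and 125 ± 66.0 in dark wild type. The call of AT5G27750 missed the threshold without dark phyB replicate 1 (adjusted p = 0.086). In dark phyAphyB, AT3G47250 (4.54 ± 0.60), AT2G16005 (4.36 ± 0.28), PME61 for a pectin methylesterase (3.75 ± 0.39) and AT2G04800 (3.58 ± 0.66) were higher, and AT4G01910 (-5.03 ± 0.23), AT4G04460 for an aspartyl protease (-4.59 ± 0.13), AT4G19500 (-4.03 ± 0.67) and AT4G02540 (-3.66 ± 0.15) were lower. Several of these differences set a clear signal against one under or within the arrays' 40th percentiles of 97.4 to 127.2, so their size is uncertain. In dark wild type the signals were 20.7 ± 6.95 for AT3G47250, 45.3 ± 9.44 for PME61, 41 ± 43.8 for AT2G04800 and 53.5 ± 11.5 for AT1G12730. In dark phyAphyB they were 10.1 ± 1.82 for AT4G01910, 52.7 ± 40 for AT4G19500 and 116 ± 19.4 for AT4G02540, and in dark phyB 44.4 ± 59.8 for AT5G23830 and 73.5 ± 55.7 for AT4G19500.

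By limma 682 probe sets differed in dark phyA (349 higher, 333 lower), 1090 in dark phyB (549 and 541) and 1694 in dark phyAphyB (865 and 829). In the red arrays, which the dark test does not use, the sign was the same for 72.7% of the phyA calls, 97% of the phyB calls and 94.3% of the phyAphyB calls, and 16.1%, 59.8% and 64.5% were called again. The phyA count rested on few arrays: it was 1443 without dark phyA replicate 1, 208 and 228 without dark phyA replicates 2 and 3, 273 and 233 without dark wild type replicates 2 and 3, 135 without both arrays of high ribosomal RNA signal and 99 from the compared groups alone. AT1G12400 missed the threshold without any of the 3 dark wild type arrays or dark phyA replicates 2 and 3 (adjusted p up to 0.15), and AT1G68250 without dark wild type replicates 2 and 3 or dark phyA replicates 2 and 3 (adjusted p up to 0.14). Without both of those phyA arrays AT1G68250 differed by -0.49 (adjusted p = 0.67), AT1G12400 by 1.64 (0.3) and AT2G14800 by 1.43 (0.079). The call of AT5G50360 was lost from the compared groups alone (adjusted p = 0.11). Of the 43 list members 4, 5 and 7 differed in dark phyA, phyB and phyAphyB, and 11, 5 and 8 when adjusted over the list alone.

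Genes that differed in the dark were neighbours more often than chance gives. Within 100 measured genes on each side of PHYA, 30 of 200 genes (15%) were called in dark phyA against 4.2% elsewhere (Fisher's exact test, two-sided, p = 3.2e-09), and in dark phyB 6 of the same 200 (3%) against 7%. Around PHYB, 36 of 200 genes (18%) were called in dark phyB against 6.6% elsewhere (exact p = 7.6e-08), and 5 (2.5%) in dark phyA against 4.5%. Dark phyB calls were as dense or denser in blocks of 50 genes away from PHYB, with 28% in a block on chromosome 4 and 26%, 24%, 22% and 22% in blocks on chromosome 5. In dark phyAphyB, 17.5% of the genes around PHYA and 21% of those around PHYB were called, against 10.6% and 10.5% elsewhere. Its densest block, with 38%, lay on chromosome 2 and reached into the genes around PHYB. Blocks away from both loci were also denser than these windows, with 28%, 26% and 26% on chromosome 4 and 26% on chromosome 5. The variance of calls per bin was 1.56, 2.85 and 2.66 times that for independent genes in phyA, phyB and phyAphyB, beyond the upper end of 1.23 of the central 95% of shuffled orders (permutation p = 1e-04 for each, the smallest they can give). For the red response of wild type it was 0.97 (permutation p = 0.6).

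**Figure D4:**
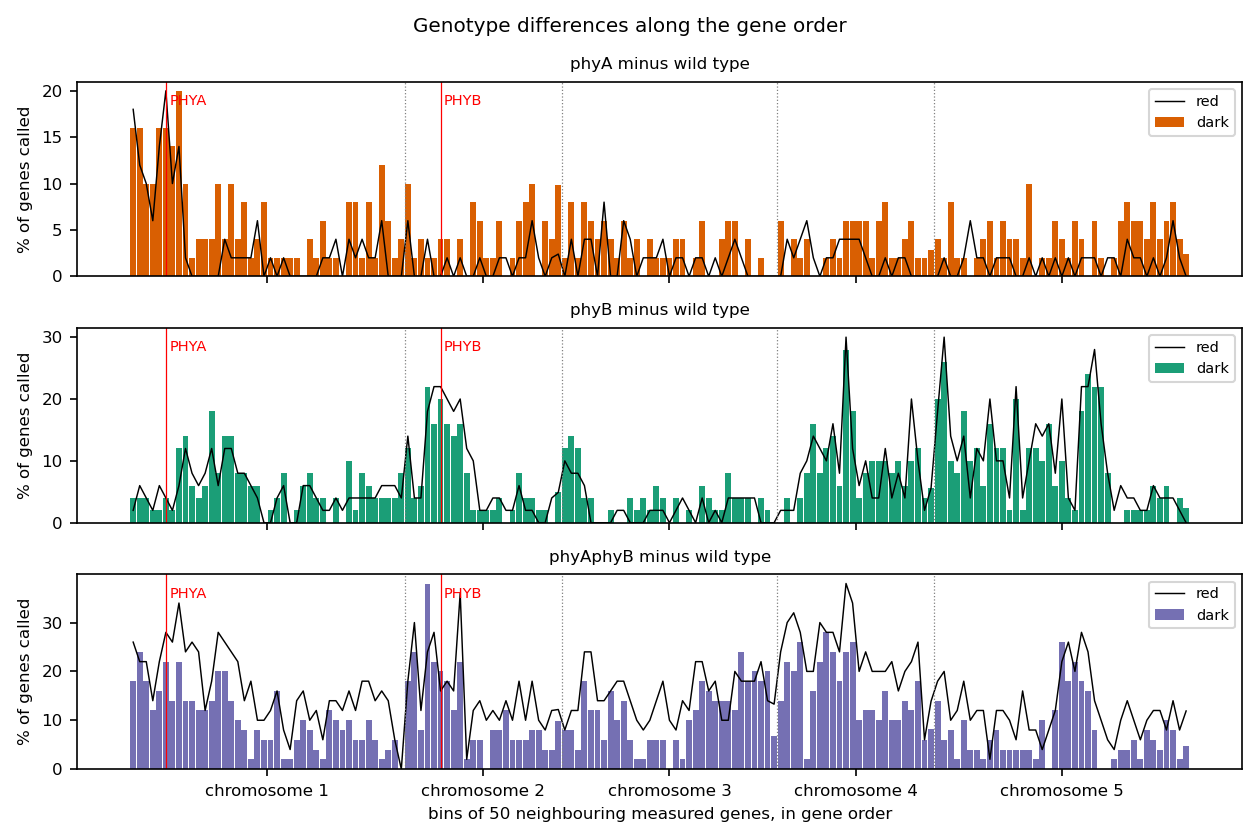
Percent of genes called as different from wild type in bins of 50 neighbouring measured genes along the 5 chromosomes, with bars for dark arrays, a black line for red arrays and red lines at PHYA and PHYB. In dark phyA 15% of the 200 genes nearest to PHYA were called, in dark phyB 18% of the 200 nearest to PHYB, and in 1 block on chromosome 4 and 1 on chromosome 5 the dark phyB share was 28% and 26%.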

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

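Groups of 3 arrays were not tested for outlying samples. The splits of the values as measured, the enrichment near each locus in red arrays and the dispersion over bins were examined only after those results had been seen. For the test of starting levels the bound was set beforehand and a demand on its interval was added after its value was seen. The other tests had their bounds set beforehand.

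Red responses that differed between genotypes were called for 100 probe sets in phyA against wild type, 282 in phyAphyB against wild type, 81 between phyA and phyB, 5 for non-additivity and 343 in the joint test. Among named genes the response in phyA differed from wild type by -2.95 for AT5G12110, -2.01 for MSRB6, -1.99 for AT1G64500, -1.88 for AT3G02910, -1.70 for AT3G21670, -0.83 for AT1G73480, 1.16 for AT3G20340, 1.19 for LEA18, 1.21 for AT5G53710 and 1.78 for AT4G10910. In phyAphyB it differed by -3.97 for SNZ, -2.88 for AT3G02910, -2.74 for AT3G63340, -2.72 for AT1G64500, -2.40 for AT3G21670, -2.27 for MSRB6, -2.13 for AT1G06000, -1.99 for UGT78D2, -1.94 for AT4G24700, -1.83 for AT5G15950, -1.52 for AT1G73480, 0.80 for HAT2, 1.02 for GH3.3, 1.65 for EXO, 1.69 for AT5G18600, 1.70 for AT4G01910, 1.71 for AT4G10910 and 1.97 for AT1G72290. A signal outside the main measurement, the 25S ribosomal RNA control probe set, read 10510 on dark phyA replicate 2 and 13570 on dark phyA replicate 3.

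With 10 splits of 6 arrays a share under 0.05 cannot be reached for a contrast of 2 groups. The real count and the highest of the other 9 splits were 973 and 1 for the wild type response, 655 and 7 for phyA, 867 and 1 for phyB, 46 and 1 for phyAphyB, 682 and 4 for dark phyA, 1090 and 1 for dark phyB, and 1694 and 0 for dark phyAphyB.

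For differences of responses, 100 splits by genotype within each light condition were drawn. Splits of the values as measured gave as large a count in 5 of 100 for phyA against wild type (real 100, highest other 409), 16 for phyAphyB against wild type (282 and 1655), 11 for phyA against phyB (81 and 2792), 100 for phyB against wild type (0 and 491), 2 for non-additivity (5 and 71) and 1 for the joint test (343 and 150). Splits that call several times the real count point to a structure of the samples. Differences between genotypes that an unequal split carries into the response are 1 such structure. With each genotype's mean removed, which leaves the differences of responses as they are, the numbers were 1 of 100 for phyA against wild type (highest other 10), 1 for phyAphyB against wild type (highest other 1), 4 for phyA against phyB (highest other 312), 100 for phyB against wild type (highest other 1), 2 for non-additivity (highest other 296) and 1 for the joint test (highest other 1). For phyA and phyAphyB against wild type only the real split reached the real count with the means removed, but 5 and 16 of 100 did as measured. The means were taken over the real genotypes, which may favour the real split, so chance is not excluded for these contrasts. For the joint test only the real split reached the real count in both versions. Both versions may favour the real split, since other splits of the values as measured mix genotypes within a group and so widen its spread. Chance is therefore not excluded there either. For phyA against phyB and for non-additivity under 5 of 100 splits gave as large a count with the means removed, but the largest of those counts were several times the real ones, so a structure other than the genotype means remains there and these counts are left open.

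A first pattern is that dark differences lay close together on the chromosomes. The spread of the dark arrays is argued against by the 93.3% of calls near PHYA (28 of 30) and 100% near PHYB (36 of 36) that had the same sign in red arrays. Sequence or strain differences carried along with each mutation remain a candidate explanation. The enrichment near the own locus in red arrays was 6.42 for phyA and 3.04 for phyB. It was 0.446 for phyA near PHYB and 0.428 for phyB near PHYA. In red phyAphyB it was 1.53 near PHYA (Fisher's exact p = 0.0024) and 1.27 near PHYB (Fisher's exact p = 0.099). The shares called there were 24.5% and 20.5%, against 12.5% near PHYA in red phyA and 20% near PHYB in red phyB. Calls elsewhere were more frequent in red phyAphyB, at 16% and 16.1%, than in red phyA (1.9%) and red phyB (6.6%), which lowers its ratios. Regulation by the missing phytochrome as the only source is not settled by the dispersion over bins (lowest value 1.56, shuffled limit 1.23), which measures the pattern itself. Against it count the 144 of 321 dark phyB differences that showed under 25% of their size in red phyAphyB arrays, which lack phytochrome B too, but a loss of phytochrome A that undoes them was not excluded.

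A second pattern is that few dark differences of phyA were called again in its red arrays (16.1%). Probe sets called on dark replicates 2 and 3 alone (1104) showed a median of 18.9% of the difference in replicate 1, where the same procedure gave 64 to 100.8% for phyB, so the state of replicates 2 and 3, the arrays with the high 25S signal, may account for many of them. Replicate 1 had the lowest correlation with its group, and this test does not say which arrays are the odd ones. A lasting effect of phyA loss stays open: of 652 calls away from PHYA, 66% had the same sign in the dark difference of phyAphyB minus phyB, which shares no array with the calls, between the bounds of 60 and 70% set for it. The phyB and phyAphyB seedlings may also differ by more than phytochrome A. Of 321 dark phyB differences of at least 2-fold, 144 showed under 25% of their size in red phyAphyB arrays, so this share alone cannot decide. A change that depends on phytochrome A in darkness and disappears in red light was not tested apart from the arrays.

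The last pattern is that 42 of the 46 calls left in phyAphyB were falls. After quantile normalization 95.3% of the calls (41 of 43) were falls, so the pattern does not hang on the choice between these scalings. The change of scaling moved the median phyAphyB response only from -0.011 to 0.001 log2 units. Both scalings assume a like distribution or mean of signal on every array, and that assumption was not tested. Low starting levels of the rising probe sets are argued against as the whole source by the point values only. The 81 rises above the median dark level retained 14.3% (interval 10.1 to 18.4) and the 45 falls above it 40.2% (32.2 to 46.6). These intervals come from draws of probe sets and are descriptive, and the spread of these shares between arrays was not measured. The upper end of the interval for rises passed the bound set beforehand. Below the median level the 148 rises retained 7.3% (5 to 9.9) and the 29 falls 24.1% (10 to 36.8), less in both directions, so a part played by low levels stays open. No biological explanation was tested, since no group lacks another photoreceptor. The labels also do not say whether the dark seedlings were handled like those given red light.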

How the results depend on the processing

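Of 1492 named gene values for 95 gene and contrast pairs under alternatives, 0 changed sign, 1409 stayed on their side of the threshold and 83 missed it, 52 of them with 1 array left out. The fit of the compared groups alone gave 233 calls for the phyA response, 24 for phyAphyB, 39 for phyA minus wild type, 16 for phyA minus phyB and 99 for dark phyA, with fewer arrays to estimate the spread. It also ended 12 named calls at unchanged size: AT5G57670 in wild type, AT5G57760 in phyAphyB, AT5G12110 and AT5G53710 for phyA minus wild type, AT1G72290 and AT3G63340 for phyAphyB minus wild type, AT1G44835, AT4G10910, AT5G12110 and WAG2 for phyA minus phyB, and AT1G68250 and AT5G50360 in dark phyA. Without a filter phyA minus phyB gave 50 and non-additivity 0, which was also 0 without the intensity trend, and the cause was not tested. Quantile normalization, the pseudocount and the stricter filter moved no count by over 1.5 times. Where probe sets were selected without wild type replicate 1 and wild type measured on it alone, the share retained in phyA was 62.4%.

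Alternatives chosen after seeing the data: array weights lean on the arrays closer to the fitted group means. Dark phyA replicates 2 and 3, with the high ribosomal RNA signal, had weights of 0.97 and 1.89, and replicate 1 had 0.3. The weighted phyA counts therefore lean on replicates 2 and 3 and do not show that these arrays are sound. The weights gave 1758, 1233, 1533 and 107 calls for the responses of wild type, phyA, phyB and phyAphyB. For differences of responses they gave 477 and 578 for phyA and phyAphyB minus wild type, 448 for phyA minus phyB and 35 for non-additivity. They gave 2771, 1699 and 2827 for dark phyA, phyB and phyAphyB, and 893 for the joint test. Leaving out dark phyA replicates 2 and 3 gave 413 for the phyA response, 135 for dark phyA and 12 for non-additivity, with the lone array assumed to vary like the other groups.

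Leaving out 1 array gave 713 to 1044 calls for wild type, 401 to 1008 for phyA, 641 to 844 for phyB, 24 to 31 for phyAphyB, 48 to 253 for phyA minus wild type, 0 to 1 for phyB minus wild type, 206 to 276 for phyAphyB minus wild type, 32 to 146 for phyA minus phyB, 0 to 21 for non-additivity, 208 to 1443 for dark phyA, 749 to 1020 for dark phyB, 1179 to 1438 for dark phyAphyB and 245 to 461 for the joint test. Retained shares were 48.9 to 56.9% in phyA, 81.2 to 90.3% in phyB and 11.3 to 13.6% in phyAphyB.

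The replicate numbers did not pair the samples: the mean correlation of deviations was -0.004 for the same number and 0.003 for different ones, and 0 of 28 pairs of groups had every correlation over 0.1. With the replicate block the wild type count was 948 (918 shared) and non-additivity 1 in place of 5. The planned check of PHYA and PHYB was not run because neither has a named probe set here. Dim signals, with the low group under every array's 40th percentile, limit HYH, SNZ, AT1G48100, MSRB6, AT1G06000, AT1G64500, AT5G57670 and AT1G72290 in wild type red light. They also limit the called red responses of SNZ, AT1G06000 and AT1G64500 in phyA, and of AT3G63340 and AT4G01910 in phyAphyB. For phyB they limit those of HYH, SNZ, MSRB6, AT1G06000, AT1G64500 and AT5G12110. In the dark they limit AT2G01090, AT1G12730 and AT2G14800 in phyA, AT3G47320, AT1G23960, AT5G27750, AT5G23830 and AT4G19500 in phyB, and AT3G47250, PME61, AT2G04800, AT4G01910 and AT4G19500 in phyAphyB.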

Other observations

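Gene families taken from symbols, chosen after the probe names were seen, moved in wild type red light at the preset correlation, and none of these calls held with an estimated correlation. Of 31 UDP-glycosyltransferase genes 4 rose and 2 fell (median log2 0.14, camera adjusted p = 0.012, and adjusted p = 0.3 with an estimated correlation). UGT78D2 rose by 1.95 and UGT76E2 by 0.91 ± 0.12, while UGT76C2, a cytokinin glucosyltransferase gene, fell by 0.68 ± 0.15. Of 9 nitrate and peptide transporter genes 3 rose (camera adjusted p = 0.0066, and adjusted p = 0.13 with an estimated correlation), and 1 of 11 glutathione transferase genes did (median 0.35, camera adjusted p = 0.0034, and adjusted p = 0.11 with an estimated correlation). Of 8 U-box ubiquitin ligase genes 1 rose (median 0.25, camera adjusted p = 0.0082, and adjusted p = 0.13 with an estimated correlation). Of 11 autophagy genes 3 fell (median -0.21, camera adjusted p = 0.0022, and adjusted p = 0.13 with an estimated correlation). The 66 plastid-encoded genes had a median of -0.52 in wild type and of 0.37, 0.40 and 0.30 in phyA, phyB and phyAphyB, where 1 fell in wild type and 4 rose in phyB. They moved together (correlation 0.488), and with that correlation estimated the adjusted p was 0.69 in wild type.

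The dark differences of phyB were often absent from the mutant that lacks both phytochromes. Of 321 dark phyB differences of at least 2-fold, 318 had the same sign in red phyB arrays and 287 kept over 50% of the difference there. In red phyAphyB arrays, which share no array with the dark test, 236 had the same sign, 131 kept over 50% and 144 showed under 25%. AT2G25450 had signals of 1030 ± 957 and 523 ± 50.8 in dark and red phyB but 10700 ± 600 and 10100 ± 498 in phyAphyB. AT3G47320 stood at 1310 ± 102 in dark phyB and 4.67 ± 4.03 in dark phyAphyB, and AT1G23960 at 1920 ± 218 and 14 ± 18.5. In the other direction, AT4G04460 stood at 3710 ± 361 in dark phyB and 156 ± 29.4 in dark phyAphyB.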
